A study of Xenopus tropicalis with 193 samples.

How the data were processed

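The series held 193 samples of whole Xenopus tropicalis embryos, in 4 groups taken from the labels: 90 poly(A)+ libraries of clutch A, 49 poly(A)+ libraries of clutch B, 48 libraries of clutch A depleted of ribosomal RNA, and 6 repeat poly(A)+ libraries of clutch A (11.5, 21.5, 30, 33, 52 and 64 hpf). The repeats had no columns of their own in the tables, so the planned mean of original and repeat did not apply, and 187 libraries were analysed. Clutch A had no library at 43 hpf. Per the labels, spike-in RNA was added to the homogenised embryos in proportion to their number.

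The deposited tables give a signal per gene, which the authors scaled to transcripts per embryo with the spike-in RNAs, and a second signal in TPM. The submitters' processing notes name TopHat2 2.010 and Cufflinks 2.1.1, and their genome build is not given in the sources used here. Within a library the transcripts per embryo were TPM times 1 factor, checked by the ratio of their 99th to 1st percentile over genes, which was at most 1.00001. A joint table of the poly(A)+ libraries of both clutches, scaled together by the authors, served as an alternative. The deposited smooth curves (unit other: transcripts per embryo from a Gaussian process of the authors) gave onsets and rates. Kernel and settings of that process are not given in the sources used here. The bounds of the authors' absolute scale were deposited with lower and upper exchanged at all 67 times for every gene, so they were taken by value, and over these times lay at a median of 30.6% and 325.3% of the curve. No table holds read counts, so the depth per sample is unknown, no counting error could be given, and no count model was used. The tables held 28276 genes, 92 ERCC and 8 ArrayControl spike-in sequences. Of 14464 gene symbols, 13488 (93.3%) matched a reference name or synonym. Isoform curves, curves of the joint scaling and of the depleted libraries, and bounds of the clutch B curves were not used here.

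Time points were grouped into windows before the data were examined: 0 to 1.5, 2 to 3.5, 4 to 5.5, 6 to 8.5, 9 to 12.5, 13 to 17.5, 18 to 24, 25 to 36, 37 to 48 and 49 to 66 hpf. The 5 comparisons were 2 to 3.5 against 0 to 1.5 hpf, 6 to 8.5 against 2 to 3.5, 13 to 17.5 against 6 to 8.5, 18 to 24 against 13 to 17.5 (all with both clutches and a term for clutch) and 49 to 66 against 18 to 24 (clutch A). Genes with at least 1 TPM in at least 4 libraries of a fit were kept. Log2 of transcripts per embryo plus a pseudocount of 0.5 TPM, which is 5066 transcripts per embryo for the first 4 comparisons and 8750 for the fifth, was fitted with limma 3.58.1 (eBayes with trend) in R 4.3.3 with data.table (version 1.17.8). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1, which is 2-fold. All tests were 2-sided, except the 1-sided permutation test of the ranks of the libraries that have a repeat. Poly(A)+ and depleted libraries were compared as differences per time point at 0 to 1.5 and 18 to 23.5 hpf, and as the difference between kinds in the first and second comparison. Clutches were compared as differences per time point over 49 time points, and as the interaction of clutch and window in the first 4 comparisons.

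The 17 gene lists were fixed before the data were examined: oocyte and germ plasm, cell cycle, replication-dependent histones, early zygotic and mesendoderm, neural, skeletal muscle, heart, blood, multiciliated cells, liver, pancreas, eye and lens, kidney, epidermis and cement gland, ribosomal proteins, oxidative phosphorylation, and Hox. Lists were tested, in transcripts per embryo, with camera at a preset correlation of 0.01 and with an estimated one. A further planned check, fry, tests whether a list's own genes changed, without setting them against other genes. Most of its values are not reported here. The ribosomal protein list was matched by the start of symbols and also holds genes of S6 kinases. Genes to name were chosen by a rule of the same date: per comparison the 10 largest rises and falls among called genes with a symbol, a mean of at least 20 TPM (0.2027 M, with M for 1000000 transcripts per embryo, or 0.35 M in the fifth comparison) in the higher window and, for the first 4, the same sign in each clutch alone, then 5 each way for the tests of clutch and kind, up to 4 called members per list, the 10 largest rates, and a set of landmark genes. Further list members and genes are named where a count was 5 or fewer, which was decided after their values were seen. Some genes that these rules chose are not reported here.

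Totals per embryo were compared by exact permutation tests, or by permutation tests with 100000 resamples where a window had 10 or more libraries, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Onset was the time at which a curve first reached 50% of its maximum up to 24 hpf. It was read for genes under 10% of it over 0 to 2 hpf and with a maximum of at least 20 TPM. For the order of Hox genes, onset was read up to 66 hpf for all 38 Hox genes, without these filters. The rate was the largest slope of the curve. Curves were read every 0.5 h to 24 hpf and every hour to 66 hpf. A first reading at all deposited times, 5 min apart, was replaced after its results were seen, because reported values must not be typed into the analysis and its column names are such numbers. In it the rates were slightly higher and myh1 stood in the place of actg1 among the 10 largest. Figures were drawn with matplotlib 3.10.9. Gaps of the extreme library to the next were tested for 72 combinations of measure and window of 4 to 10 libraries, on library measures alone. Other splits of the samples were fitted on the compared windows alone, so their counts for the real split differ slightly from those reported. Tested on simulated data, the fits recovered 93% to 100% of 100 genes with a change of log2 1.5 or 3, and called 0 to 4 unchanged genes. The simulated noise was independent around a flat mean, with no trend in time and no correlation of neighbouring libraries. It therefore gives no error rate for the real time course.

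The alternatives fixed before the data were examined were a pseudocount of 0.1 or 2 TPM, no filter, a minimum of 5 TPM, TPM instead of transcripts per embryo, eBayes robust and without trend, linear time within windows, each clutch alone, time point as a replicate block, the joint table, each time point left out in turn, totals without the 10 most abundant genes, and for the curves another onset threshold and measured values. Alternatives chosen after seeing the data were a scale from each library's own ERCC sum, fits without the clutch B library of 22.5 hpf, without 22.5 hpf in both clutches, without the 52 hpf library or without the clutch A time points that have a repeat, clutch differences paired by time point, and the joint table for the level of the clutches. Checks that need gene sequences or lengths were not made.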

Results

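RNA of whole embryos of the frog Xenopus tropicalis was sequenced from fertilisation to 66 h post fertilisation (hpf), to follow the absolute number of transcripts per embryo through development. Poly(A)+ libraries covered 90 time points of clutch A, up to 66 hpf, and 49 time points of clutch B, up to 24 hpf. A clutch is a set of eggs fertilised together. Libraries depleted of ribosomal RNA, which also hold transcripts with a short or absent poly(A) tail, covered 48 time points of clutch A, up to 23.5 hpf. Each library pooled the embryos of 1 time point, and libraries of neighbouring time points served as replicates within a window of time. The p-values therefore measure the spread between neighbouring time points of 2 clutches, not between many matings. The tables held 28276 genes, of which 14464 had a symbol. The ERCC spike-in RNAs that were added per embryo took 1.01% to 8.27% of the TPM (transcripts per 1000000) in clutch A, 1.46% to 7.32% in clutch B and 3.85% to 9.91% in the depleted libraries. The tables give no read counts, so the depth of each library is unknown. The genome build is not given in the sources used here, and gene positions were not analysed here. The windows compared were 0 to 1.5 hpf and 2 to 3.5 hpf, both in cleavage stages (n = 4 libraries per clutch and kind), 6 to 8.5 hpf, around gastrulation (n = 6), 13 to 17.5 hpf, around neurulation (n = 10), 18 to 24 hpf, in tailbud embryos (n = 13, and 12 for the depleted libraries), and 49 to 66 hpf, in tadpoles (n = 18, clutch A). Gene levels below are given in M (1000000 transcripts) per embryo of clutch A, as mean ± SD over these libraries, while log2 changes and their SE up to 24 hpf come from fits of both clutches.

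The first question was how much messenger RNA an embryo held. The summed poly(A)+ transcripts of clutch A rose from 5.49 ± 0.692 G (1000000000 transcripts) per embryo at 0 to 1.5 hpf to 7.70 ± 0.729 G at 2 to 3.5 hpf, 9.09 ± 0.251 G at 6 to 8.5 hpf, 11.8 ± 1.06 G at 13 to 17.5 hpf, 16.3 ± 1.46 G at 18 to 24 hpf and 32.5 ± 2.86 G at 49 to 66 hpf. Clutch B rose from 5.08 ± 0.699 to 7.46 ± 0.825, 9.66 ± 0.18, 12.8 ± 0.659 and 15.6 ± 1.84 G over the windows up to 24 hpf. The depleted libraries of clutch A started higher, at 10.2 ± 0.132 G, fell to 9.70 ± 0.181 and 8.04 ± 0.17 G, and then rose to 12.1 ± 1.26 and 16.9 ± 1.67 G. In each of these 13 comparisons every library of the later window lay on the same side of all earlier ones. The 2-sided p was 0.0286 from 0 to 1.5 to 2 to 3.5 hpf in each series (exact permutation, the smallest that 4 against 4 libraries can give), and 0.00476 for the next step in each series (exact permutation, the smallest possible). The later steps gave permutation p between 1e-05, the smallest possible, and 0.00018. The 2 clutches differed by a mean log2 of -0.03 (SD 0.10) over 49 shared time points, with clutch A higher at 21 of them (2-sided permutation p = 0.0734). The SDs given here do not cover the absolute scale itself. The authors' bounds of that scale lay at a median of 30.6% and 325.3% of the gene curves of clutch A. Around their neighbours in time the deposited totals varied with an SD of 0.00842 log2 in clutch A, against 0.175 for the summed ERCC transcripts, so totals of neighbouring time points are not independent measurements. With each library scaled by its own ERCC sum, a setting chosen after seeing the data, 4 of these steps were no longer called. The first step was 0.42 log2 in clutch A (exact permutation p = 0.0857, 2-sided), 0.48 in clutch B (exact permutation p = 0.0571) and -0.08 in the depleted libraries (exact permutation p = 0.2), and the second step of clutch A was 0.26 (exact permutation p = 0.0524).

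**Figure D1:**
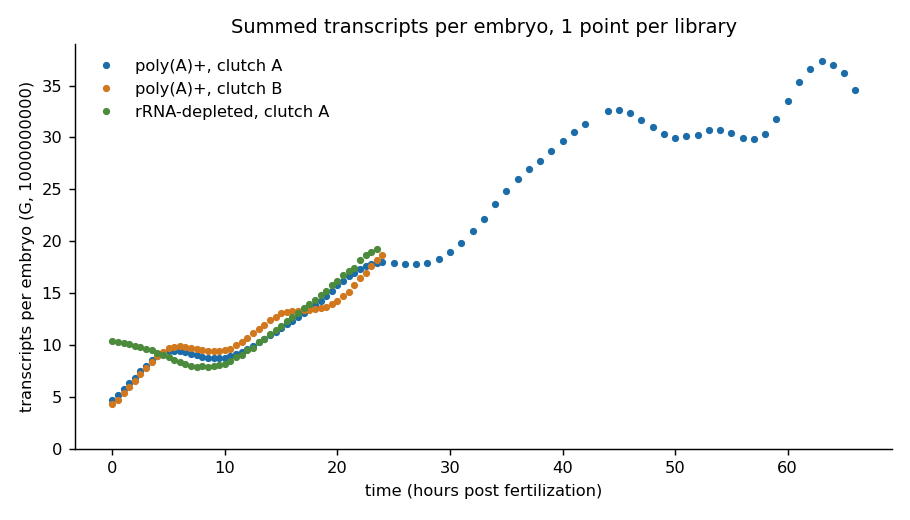
Summed transcripts per embryo (G, vertical axis) of each library against time (hpf, horizontal axis) for poly(A)+ clutch A, poly(A)+ clutch B and the depleted libraries of clutch A. The mean of clutch A rose from 5.49 G at 0 to 1.5 hpf to 32.5 G at 49 to 66 hpf, while the depleted libraries fell from 10.2 to 8.04 G before they rose.

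The comparison of 2 to 3.5 hpf with 0 to 1.5 hpf asked which transcripts changed during cleavage, before the main onset of transcription from the embryo's genome. In poly(A)+ libraries the kinase gene pak4 rose from 0.0451 ± 0.0524 to 0.564 ± 0.246 M per embryo (log2 3.95, SE 0.28, n = 4 per clutch and window), and the peptidase gene dpp8 rose from 0.0284 ± 0.0338 to 0.478 ± 0.245 M (log2 4.18, SE 0.22). The RNA-binding protein gene lsm12 rose from 0.279 ± 0.313 to 2.64 ± 0.962 M (log2 3.82, SE 0.22). Other large rises were those of wdr46 (log2 3.99), dusp11.2 (3.92), adrbk2 (3.89), arl9 (3.87), slc38a9 (3.83), ngrn (3.78) and dmap1 (3.77). In the opposite direction, eif2ak3, which encodes a stress kinase of the endoplasmic reticulum, fell from 2.46 ± 0.655 to 0.536 ± 0.167 M (log2 -2.25, SE 0.20), and kif11, a mitotic motor, fell from 2.70 ± 1.20 to 0.684 ± 0.0698 M (log2 -1.95, SE 0.16). The other large falls were those of anubl1 (-2.23), melk (-2.22), rnd3 (-1.93), trim37 (-1.93), fmn2 (-1.91), cep135 (-1.77), nr1d1 (-1.76) and ap1m2 (-1.74). By limma, 6411 of 18289 genes were called higher and 68 lower, at an adjusted p under 0.05 and a change of at least 2-fold. The median log2 change of all genes was 0.53, and 0.24 in TPM, where 4555 genes were higher and 203 lower.

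From 0 to 1.5 to 2 to 3.5 hpf, of 48 tested cell cycle genes, 13 rose and 4 fell, or 11 and 7 in TPM (adjusted p = 0.416 with an estimated correlation), although the list's median was 0.01 and was negative, -0.48, in TPM. Cyclin ccnb3 rose by log2 3.68, the replication genes mcm2, mcm4 and pcna rose by 3.25, 2.77 and 2.27, and kif11, aurka (-1.56), aurkb (-1.04) and cdk2 fell. Of 31 oocyte and germ plasm genes, 12 rose and 1, trim36 (log2 -1.48), fell, or 8 and 2 in TPM (adjusted p = 0.98 with an estimated correlation). Among them were gdf9 (2.81), zar1 (2.73), otx1 (2.58), zp3.2 (2.13) and the T-box gene vegt (1.49, from 2.18 ± 0.948 to 5.01 ± 0.732 M). Of 74 genes of oxidative phosphorylation, 43 rose in transcripts per embryo and 22 in TPM (adjusted p = 0.454 with an estimated correlation), with atp5sl at 2.53, ndufa5 at 2.49, cox5a at 2.44 and ndufb8 at 2.27. Of 85 genes on the ribosomal protein list, 10 rose, and 6 in TPM (adjusted p = 0.891 with an estimated correlation). The list's median was 0.34 and turned negative in TPM, at -0.14, and its largest rises were those of rps6ka1 (3.37), rps6kb1 (1.91), rps6ka5 (1.83) and rps6ka3 (1.78), which encode kinases that act on or are related to regulators of the ribosome and are not parts of it. Of 25 genes of epidermis and cement gland 5 rose, namely krt8.2 (2.18), krt12 (2.16), grhl1 (2.06), krt18 (1.93) and grhl2 (1.05), with adjusted p = 0.567 with an estimated correlation. The 4 of 27 multiciliated cell genes that rose were rsph1 (1.37), rsph9 (1.23), rfx2 (1.11) and rfx3 (1.04), and 0 rose in TPM, with adjusted p = 0.611 with an estimated correlation, and the 2 of 35 neural genes were sox11 (1.85) and tubb2b (1.49), with adjusted p = 0.4 with an estimated correlation. Of the landmark genes, eef1a1, a translation elongation factor, rose from 0.431 ± 0.24 to 2.14 ± 0.805 M (log2 2.39, SE 0.20) and actb rose from 0.173 ± 0.0477 to 0.617 ± 0.233 M (log2 1.68). The maternal genes ccnb1 (0.02), ccna1 (0.04), mos (-0.04), h1foo (0.06), gdf1 (0.18) and odc1 (-0.01, or -0.51 in TPM) were not called. Counts adjusted over the list alone equalled the counts over all genes for every list in each of the 5 window comparisons, except that nodal3.1 (1.03), called as 1 of 50 early zygotic genes, was not called over its list alone. No list call of camera in any of these comparisons held with an estimated correlation, the lowest adjusted p being 0.0695. Several lists differed in sign between median and test, because camera set them against all other genes, whose median rose.

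The depleted libraries of the same clutch and times showed whether the amount of these transcripts changed. Total pak4 was 0.775 M at 0 to 1.5 hpf and 0.780 M at 2 to 3.5 hpf, lsm12 was 4.46 and 4.43 M, pcna was 13.4 and 13.0 M, and actb was 16.6 and 15.8 M. Of the 6411 genes that rose in poly(A)+ libraries, 6395 were measured in the depleted libraries, where their median log2 change was -0.07 (quartiles -0.14 and -0.01) against 1.68 in the poly(A)+ libraries. Among all 17890 genes tested there, limma called 0 higher, with 436 genes at an unadjusted p under 0.05. It called 3 lower, namely rpl37 (log2 -1.46), ift43 (-1.13) and a gene without a symbol (-1.45), which are named because the count is small. The test of the difference between the 2 kinds of library, paired by time point, called 6562 genes, with 6495 changing more upward in poly(A)+ libraries and 67 more downward, and 5975 of the 6411 were among those called. In TPM these counts were 4461 and 203. The 5 largest differences upward were those of hs3st1 (log2 4.38, SE 0.40), dpp8 (4.30), dusp11.2 (4.21), slc38a9 (4.05) and wdr46 (4.05). The largest downward were those of trim37 (-2.03), anubl1 (-2.04), eif2ak3 (-2.28), melk (-2.32) and mir427 (-3.24). The last was listed at 0 in poly(A)+ libraries at 0 to 1.5 hpf and reached 0.212 M in depleted ones at 2 to 3.5 hpf. As mir427 could not fall from 0 in poly(A)+ libraries, its negative difference means a rise in depleted ones. It was still not called higher there. The count of 0 genes called higher in depleted libraries therefore does not show that no total RNA rose. Upward differences covered 56 of 74 genes of oxidative phosphorylation and 41 of 85 on the ribosomal protein list.

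The comparison of 6 to 8.5 hpf with 2 to 3.5 hpf spanned the activation of the embryo's own genome. The transcription factor gene oct91 rose from 0.000929 ± 0.000671 to 6.95 ± 3.08 M per embryo (log2 10.06, SE 0.53), foxa4 rose to 4.78 ± 0.911 M (9.77, SE 0.41) and mixer, a gene of the endoderm, rose to 3.12 ± 0.865 M (9.11, SE 0.55). The metabolic enzyme gene gatm rose to 5.92 ± 2.99 M (9.09, SE 0.35), and the neural gene sox2 from 0.00476 ± 0.000963 to 2.40 ± 0.844 M (7.68, SE 0.28). Because these levels start near 0, the log2 values depend on the added pseudocount. The meiotic regulator fbxo43 fell from 3.34 ± 0.919 to 0.105 ± 0.121 M (log2 -5.57, SE 0.38), btg4, which links messenger RNAs to deadenylation, from 9.37 ± 1.21 to 0.408 ± 0.468 M (-5.05), and the cyclin gene ccna1 from 24.7 ± 0.884 to 2.44 ± 2.24 M (-3.97). By limma 3279 of 18289 genes rose and 1288 fell. The median log2 change was 0.21, or 0.05 in TPM, where the higher share moved from 71.8% to 57.8% (2561 higher and 1868 lower).

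Further large rises were those of atp1b2 (9.00), krt (8.96), tfap2a (8.81), gs17 (8.77), zic1 (8.75) and krt5.7 (8.72). Of 50 early zygotic and mesendoderm genes, 49 rose (adjusted p = 0.0695 with an estimated correlation), among them eomes (8.59), the mesoderm gene t (8.50, to 2.31 ± 1.16 M), sox17a (8.17), mix1 (8.13), and the organiser genes chrd (7.51) and gsc (7.37). Of 25 genes of epidermis and cement gland, 16 rose, led by krt5.7 and foxi4.2 (8.59), and 1, ca12 (-1.03), fell, or 2 in TPM (adjusted p = 0.342 with an estimated correlation). Of 35 neural genes 14 rose (adjusted p = 0.4 with an estimated correlation), led by zic1. Of 17 kidney genes 9 rose, among them osr2 (6.61), slc12a3.2 (6.61) and irx1 (6.10), with adjusted p = 0.342 with an estimated correlation. The 4 muscle genes that rose of 31 tested were myf5 (2.49), actc1 (2.38), tnni1.2 (1.64) and myod1 (1.46), and the 2 of 17 eye and lens genes were crx (8.58) and rpe65 (2.37). Of 38 Hox genes 6 rose, with hoxd1 at 3.57, and 7 of 27 multiciliated cell genes rose, with foxj1, their master regulator, at 4.61. Of 85 ribosomal protein genes 60 rose and 3 fell (adjusted p = 0.4 with an estimated correlation), with rps2 at 3.33 and rpl37 at 2.94, and of 74 oxidative phosphorylation genes 22 rose, and 14 in TPM (adjusted p = 0.513 with an estimated correlation). Of 12 replication-dependent histone genes 7 rose and 2 fell, with hist2h3c at 3.46, hist1h2aa at -2.48 and hist1h2am at -2.38 (adjusted p = 0.436 with an estimated correlation).

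From 2 to 3.5 to 6 to 8.5 hpf, of 31 oocyte and germ plasm genes 10 fell and 5 rose, while in TPM 11 fell and 0 rose (adjusted p = 0.473 with an estimated correlation). The translational regulator cpeb1 fell from 5.50 ± 0.327 to 0.380 ± 0.408 M (-4.41), zar1l by log2 -2.29, the linker histone h1foo by log2 -2.20 and gdf1 by log2 -1.12, while zp4 (1.26), zp3.2 (1.21), vegt (1.17), tdrd6 (1.17) and ddx4 (1.00) rose. Of 48 cell cycle genes 12 fell and 9 rose, with ccnb1 at -2.53 (25.7 ± 0.918 to 6.34 ± 5.56 M), cdc25b at 6.52 and ccne2 at 4.17 (adjusted p = 0.473 with an estimated correlation). The list's median was -0.04 and its mean 0.04. The largest other falls were those of zfp36l2.2 (-5.07), fbxl8 (-5.03), heca (-4.72), zfp36l2.1 (-4.44), socs1 (-4.09) and pdp1 (-3.95). In this interval the difference between the kinds of library was called for 3271 genes, with 3087 higher and 184 lower in poly(A)+ libraries, and 1687 and 532 in TPM, where the higher share was 76% instead of 94.4%. The gene actb rose in poly(A)+ libraries by log2 3.29 and was -0.54 in depleted ones, and eef1a1 rose by log2 3.68, with 1.72 in depleted ones. The largest differences upward were those of ndufc2 (6.09), mixer (4.83), mrps25 (4.48), ska2 (4.46) and tubb2c (4.42), and the largest downward were those of map4 (-2.15), cpeb1 (-2.10), menf.2 (-1.85), rab11fip5 (-1.84) and fzd1 (-1.77). Upward differences covered 53 of 74 genes of oxidative phosphorylation and 53 of 85 ribosomal protein genes.

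**Figure D2:**
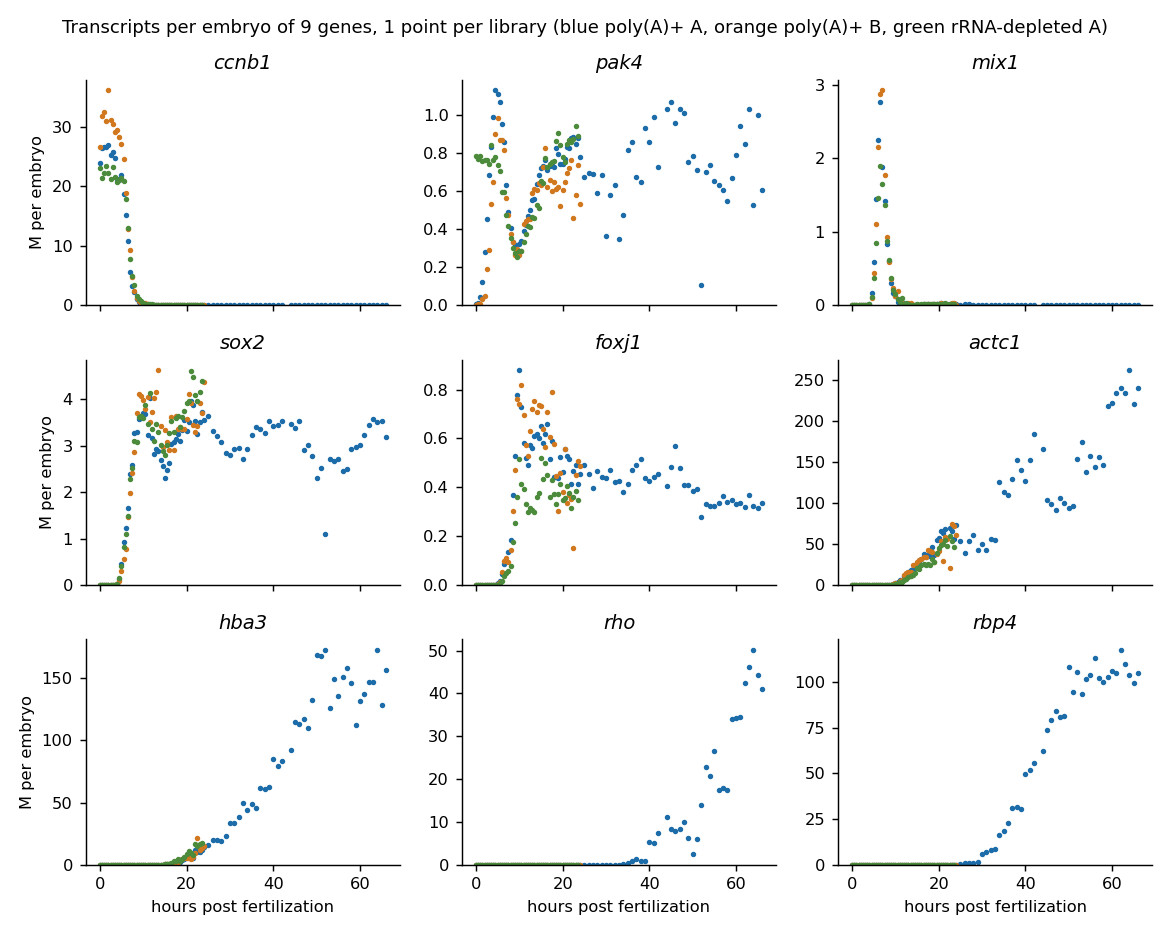
Transcripts per embryo (M, linear axis from 0) against time (hpf) for 9 genes, with a point per library of poly(A)+ clutch A, poly(A)+ clutch B and the depleted libraries of clutch A. At 0 to 1.5 hpf pak4 stood at 0.0451 M in poly(A)+ and 0.775 M in depleted libraries, and rbp4 reached 103 M at 49 to 66 hpf.

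The comparison of 13 to 17.5 hpf with 6 to 8.5 hpf followed the embryo from gastrulation into neurulation. The myosin light chain gene mylpf rose from 0.00249 ± 0.00517 to 15.5 ± 6.96 M per embryo (log2 10.99, SE 0.37, n = 6 and 10 per clutch), the cardiac and skeletal actin gene actc1 from 0.0394 ± 0.0434 to 27.5 ± 7.82 M (9.74, SE 0.32), and act3 was listed at 0 in clutch A before and at 10.0 ± 5.13 M after. The keratin gene krt19 rose from 0.0783 ± 0.142 to 15.0 ± 3.83 M (9.43, SE 0.35) and the complement gene c3 from 0.0037 ± 0.00525 to 4.01 ± 0.884 M (9.08, SE 0.30). The Nodal co-receptor gene tdgf1 fell from 3.55 ± 1.09 to 0.00454 ± 0.0034 M (-8.49, SE 0.34), vegt from 11.3 ± 1.72 to 0.175 ± 0.119 M (-5.92), oct25 from 12.4 ± 2.47 to 0.125 ± 0.0808 M (-6.38) and ccnb1 from 6.34 ± 5.56 to 0.0262 ± 0.0121 M (-7.00). By limma 6028 genes rose and 3578 fell. The median log2 change was 0.29, or 0.00 in TPM, where 5067 rose and 4768 fell, which is 51.5% higher instead of 62.8%.

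Of 31 skeletal muscle genes 29 rose (adjusted p = 0.373 with an estimated correlation), among them des.1 (9.64), atp2a1 (9.11) and the muscle regulator myod1 (6.89, to 2.48 ± 0.215 M). All 38 tested Hox genes rose (adjusted p = 0.355 with an estimated correlation), with hoxb8 at 7.74, hoxc4 at 7.47 and hoxb9 at 7.22. Of 27 multiciliated cell genes 23 rose, and in TPM 1 fell as well (adjusted p = 0.355 with an estimated correlation), with efhc2 at 6.25. Of 35 neural genes 24 rose and 3, among them nefl (-1.64) and zic1 (-1.19), fell, or 23 and 5 in TPM, with ncam1 at 6.79 and pax6 at 7.04 among the rises (adjusted p = 0.4 with an estimated correlation). Of 12 heart genes 10 rose, with hand1 at 8.89, isl1 at 6.26 and nkx2-5 at 5.79 (adjusted p = 0.373 with an estimated correlation). Of 16 blood genes 15 rose, with mpo at 7.41 and tal1 at 6.26 (adjusted p = 0.4 with an estimated correlation), and of 19 liver genes 11 rose (adjusted p = 0.473 with an estimated correlation). The 5 pancreas genes that rose of 9 tested were pnliprp2 (7.00), sst (6.19), pdx1 (4.18), cpb1 (1.18) and cpa1 (1.03), and in TPM 4 rose and 1 fell. Of 17 eye and lens genes 11 rose, with rax at 6.30 and vsx1 at 4.87, and crx (-3.36) fell (adjusted p = 0.515 with an estimated correlation). Of 17 kidney genes 11 rose, with pax8 at 6.39, and nphs1 (-1.80) fell (adjusted p = 0.4 with an estimated correlation). Of 25 genes of epidermis and cement gland 17 rose, with agr2 at 8.24, and cldn6.1 (-3.52) fell (adjusted p = 0.373 with an estimated correlation). Of 85 ribosomal protein genes 78 rose and 2 fell, with rpl31 at 3.15 (adjusted p = 0.4 with an estimated correlation), and of 74 oxidative phosphorylation genes 24 rose and 6 fell (adjusted p = 0.83 with an estimated correlation), with ndufc2 at 3.14 and ndufaf2 at -2.41. The glycolytic gene gapdh rose by log2 5.01, dnase1l3 by 10.11, slc18a1 by 9.37 and pnliprp3 by 9.14.

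From 6 to 8.5 to 13 to 17.5 hpf, of 31 oocyte and germ plasm genes 25 fell and 1, wnt11 (4.47), rose (adjusted p = 0.332 with an estimated correlation), with zar1l at -6.47, gdf1 at -5.50, gdf9 at -5.42, h1foo at -5.34 and mos at -4.56. Of 48 cell cycle genes 17 fell and 4, mcm6.2 (2.47), top2a (1.49), bub1b (1.45) and mcm5 (1.05), rose, with birc5.1 at -5.64, wee2 at -4.49 and mcm3 at -4.33 among the falls (adjusted p = 0.355 with an estimated correlation). Of 12 histone genes 9 fell and 1, hist1h3g (1.17), rose, or 9 and 0 in TPM (adjusted p = 0.263 with an estimated correlation), with hist1h2am at -6.17. Of 50 early zygotic genes 26 fell and 10 rose (adjusted p = 0.513 with an estimated correlation), with mixer at -7.49, mix1 at -6.99 and nodal3.1 at -6.02. Other large falls were those of oct60 (-6.62) and hpdl (-6.18), and odc1 fell by log2 -1.17.

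The comparison of 18 to 24 hpf with 13 to 17.5 hpf covered the tailbud embryo. The globin gene hbd rose from 0.0890 ± 0.164 to 4.92 ± 3.50 M per embryo (log2 7.48, SE 0.36, n = 10 and 13 per clutch), and hba3 from 0.565 ± 0.694 to 7.43 ± 3.78 M (5.23, SE 0.37). The lens crystallin gene cryba1 rose from 0.0310 ± 0.0435 to 1.14 ± 0.748 M (5.55, SE 0.29), the muscle creatine kinase gene ckm from 0.339 ± 0.281 to 5.58 ± 3.77 M (4.23, SE 0.29) and the apolipoprotein gene apoa1 from 0.0926 ± 0.0615 to 1.83 ± 1.48 M (3.79, SE 0.28). The largest fall was that of uvs.2, a hatching enzyme gene, from 1.65 ± 0.72 to 0.0864 ± 0.0927 M (-4.93, SE 0.38). By limma 4396 genes rose and 447 fell. The median log2 change was 0.46, or 0.13 in TPM, where 2515 rose and 722 fell, which is 77.7% higher instead of 90.8%. In this window the clutch B library of 22.5 hpf stood apart from its neighbours, with 36 genes higher and 2661 lower by at least 1 log2.

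Of 16 blood genes 9 rose (adjusted p = 0.473 with an estimated correlation), hbe1 among them at 6.89. Of 31 muscle genes 23 rose, with tnnc2 at 4.00 (1.92 ± 1.94 to 13.4 ± 4.36 M), pgam2 at 4.00 and cav3.2 at 4.05, and in TPM 20 rose and 2 fell (adjusted p = 0.579 with an estimated correlation). Of 19 liver genes 15 rose, with fgb at 3.49 (adjusted p = 0.454 with an estimated correlation), and of 17 eye and lens genes 11 rose, with crybb1 at 4.18, and in TPM 10 rose and 1 fell (adjusted p = 0.437 with an estimated correlation). The 5 of 12 heart genes that rose were myl4 (4.82), myl7 (2.36), hand2 (1.93), tbx5 (1.88) and tnni3 (1.72), and the 3 of 17 kidney genes were slc5a1.2 (3.14), wt1 (2.52) and slc5a1.1 (1.44), while 3 kidney genes also fell in TPM. Of 35 neural genes 11 rose, with gap43 at 3.71 and ina at 3.47, and in TPM 3 fell as well. Of 74 oxidative phosphorylation genes 26 rose, and 11 in TPM, with cox8a at 3.22 (adjusted p = 0.4 with an estimated correlation), and of 85 ribosomal protein genes 42 rose, and 4 in TPM (adjusted p = 0.416 with an estimated correlation). The Hox list held 6 genes that rose, with hoxc13 at 1.99 and hoxa13 at 1.95, and 1 that fell, hoxd1 (-1.21), or 4 and 2 in TPM, and its median turned from 0.23 to -0.12 in TPM. The multiciliated cell list held 2 that rose, tekt3 (2.13) among them, and 2 that fell, cdc20b (-2.83) and ccno (-1.87), or 1 and 3 in TPM, and its median turned from 0.30 to -0.06 in TPM (adjusted p = 0.515 with an estimated correlation). Of 31 oocyte and germ plasm genes 12 fell (adjusted p = 0.257 with an estimated correlation), with zp2 at -1.83, and wnt11 (1.13) rose, while in TPM 14 fell and 0 rose. Of 50 early zygotic genes 19 fell (adjusted p = 0.342 with an estimated correlation), with admp at -3.89, gsc at -3.07 and chrd at -2.09, and vgll2 (1.27) rose, while in TPM 23 fell and 0 rose. Of 48 cell cycle genes 7 fell, with ccna1 at -3.38 and rrm2.1 at -2.03, while the list's median was 0.14 and turned to -0.21 in TPM (adjusted p = 0.4 with an estimated correlation). The other large rises were those of g6pc2 (7.06), ocm (6.82), g6pc (5.95), ocm.2 (5.80), myom2 (5.46) and nt5c1b (5.29), and the other large falls those of spam1 (-3.83), has-rs (-3.70), ugt3a2 (-3.31), vgll3 (-3.31), ugdh.2 (-3.16), oct91 (-3.15) and hal.1 (-2.79). The genes actc1 (0.90), foxj1 (-0.57) and myod1 (-0.89) were not called.

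The comparison of 49 to 66 hpf with 18 to 24 hpf, in clutch A alone, covered the change to a swimming tadpole with working organs. The retinol carrier gene rbp4 rose from 0.0177 ± 0.0261 to 103 ± 7.89 M per embryo (log2 12.37, SE 0.32, n = 13 and 18), and ttr, a carrier of thyroid hormone, from 0.482 ± 0.191 to 108 ± 19.9 M (7.85, SE 0.28). The gut lipid carrier gene fabp2 rose from 0.0117 ± 0.00522 to 29.1 ± 4.70 M (10.50, SE 0.35), the rod photopigment gene rho from 0.00675 ± 0.00207 to 26.6 ± 14.9 M (10.42, SE 0.38) and hbd from 4.92 ± 3.50 to 251 ± 25.9 M (6.10, SE 0.33). The protease gene tll1 fell from 3.02 ± 0.601 to 0.0189 ± 0.0141 M (-6.92, SE 0.30) and the keratin gene krt from 38.3 ± 11.4 to 0.978 ± 0.165 M (-5.23, SE 0.25). By limma 8259 of 19643 genes rose and 1105 fell. The median log2 change was 0.75, or -0.11 in TPM, where 4093 rose and 3614 fell, which is 53.1% higher instead of 88.2%. The library of 52 hpf stood apart from its neighbours, with 9 genes higher and 4260 lower by at least 1 log2.

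Of 20 liver genes 19 rose (adjusted p = 0.373 with an estimated correlation), with apoa4 at 8.11 and fgg at 8.06 (in TPM 17 rose and 1 fell), and of 33 eye and lens genes 32 rose (adjusted p = 0.4 with an estimated correlation), with opn1lw at 9.98 and gnat1 at 7.29 (in TPM 27 rose and 1 fell). Of 17 pancreas genes 13 rose and 1, amy2b (-3.26), fell (adjusted p = 0.724 with an estimated correlation). The digestive enzyme gene cpa1 rose by log2 6.97 and pla2g1b by log2 5.62, while prss2 was listed at 0 before and at 0.338 M after. Of 75 oxidative phosphorylation genes 69 rose, and 55 in TPM, with cox8a at 6.25 and cox4i2 at 5.40 (adjusted p = 0.373 with an estimated correlation). Of 86 ribosomal protein genes 84 rose, while in TPM 18 rose and 2 fell (adjusted p = 0.4 with an estimated correlation). Of 15 heart genes 9 rose, with myl7 at 5.90, and nkx2-5 (-1.13) fell, or 8 and 3 in TPM, and of 18 blood genes 11 rose, with hba2 at 6.63 and gata1 at 4.82, and spib (-1.27) fell, or 8 and 5 in TPM. Of 36 muscle genes 21 rose, with pvalb at 4.61 and ckm at 4.14, and 5 fell, namely ttn (-2.40), pgam2 (-1.80), myod1 (-1.57), neb (-1.21) and myh4 (-1.10), or 16 and 8 in TPM, with adjusted p = 0.98 with an estimated correlation.

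In the same comparison, of 38 Hox genes 15 fell and 3, hoxa13 (2.58), hoxa4 (2.05) and hoxc12 (1.07), rose (adjusted p = 0.373 with an estimated correlation), with hoxb1 at -4.62, hoxb9 at -3.15 and hoxb8 at -3.13, and in TPM 26 fell and 2 rose. Of 50 early zygotic genes 20 fell, with wnt8a at -4.52 and szl at -3.95, and 4, gsc (3.86), frzb (3.43), eomes (2.20) and nog (1.23), rose, or 29 and 3 in TPM (adjusted p = 0.263 with an estimated correlation). Of 31 oocyte and germ plasm genes 11 fell and 5 rose, or 17 and 3 in TPM (adjusted p = 0.257 with an estimated correlation). The germ line genes dazl and ddx4 fell by log2 -4.20 and -2.94 and zpd by -3.99, while grip2 (2.60), cpeb1 (2.04), gdf9 (1.83), sybu (1.54) and mos (1.53, from 0.0591 ± 0.012 to 0.186 ± 0.0233 M) rose. Of 35 neural genes 10 rose and 9 fell, but 8 rose and 20 fell in TPM, with nefl at 3.62 (adjusted p = 0.4 with an estimated correlation), and of 48 cell cycle genes 3 rose and 3 fell, but 22 fell in TPM (adjusted p = 0.355 with an estimated correlation). The cell cycle genes called were ccna1 (1.83), pcna (1.28), cdk1 (1.10), mcm6 (-1.69), mki67 (-1.25) and rrm2.1 (-1.16). Of 26 genes of epidermis and cement gland 5 rose and 4 fell, with krt15 at 8.02, but 2 rose and 16 fell in TPM (adjusted p = 0.373 with an estimated correlation), and of 21 kidney genes 6 rose and 5 fell, with slc5a2 at 4.75, but 5 rose and 9 fell in TPM (adjusted p = 0.454 with an estimated correlation). Of 27 multiciliated cell genes 2, cdc20b (2.35) and ccno (1.76), rose and 5, ccdc39 (-1.81), foxn4 (-1.44), dnah5 (-1.33), tekt2 (-1.09) and tuba1a (-1.05), fell, and in TPM 1 rose and 19 fell (adjusted p = 0.355 with an estimated correlation). Other large rises were those of thdl18 (9.46), tm4sf4 (8.43), fabp1 (8.42), rbp2 (8.42), hpd (8.38) and tst (8.24), and other large falls those of tll2 (-6.08), cdx4 (-5.62), slc10a1 (-5.53), crisp1 (-5.34), pcdh8l (-5.16), ripply2.2 (-4.91) and 10a1.1 (-4.37).

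**Figure D3:**
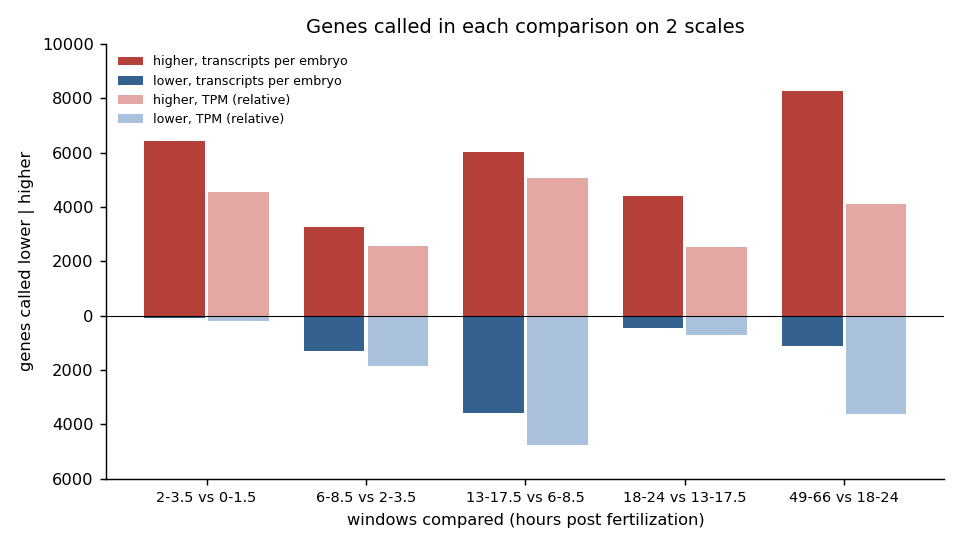
Genes called higher (bars above 0) and lower (bars below 0) in each of the 5 window comparisons, in transcripts per embryo and in TPM. From 18 to 24 hpf to 49 to 66 hpf, 8259 genes were higher and 1105 lower per embryo, against 4093 and 3614 in TPM.

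The series was made to measure absolute numbers, so calls per embryo were set against calls in TPM. No gene had opposite calls in any of the 5 comparisons, which follows from the scales. Opposite calls would need a shift of scale well above those found. At the median gene the absolute change exceeded the relative one by log2 0.38, 0.28, 0.35, 0.35 and 0.94 over the 5 comparisons in order of time. The sign of the fitted change differed in 14.8%, 13.5%, 8.10%, 19.1% and 30.9% of genes, in the same order. All genes of a library share 1 scale factor, so these are mainly genes with a change that was small beside the shift. In the last comparison 4166 genes were higher per embryo alone and 2509 were lower in TPM alone. The oocyte kinase gene mos, for example, rose by log2 1.53 per embryo and was 0.62 in TPM, and krt fell by log2 -5.23 per embryo and -6.19 in TPM.

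Poly(A)+ and depleted libraries of clutch A were compared directly at the start and the end of their shared time. At 0 to 1.5 hpf the glycolytic gene tpi1 stood at 0.0253 M in poly(A)+ and 11.3 M in depleted libraries (log2 -8.72, SE 0.21, n = 4 pairs), the histone variant gene h2afx at 0.0430 against 11.6 M (-8.05, SE 0.20) and pcna at 0.165 against 13.4 M (-6.42). The genes mgst3 (-7.59), rhou (-7.43) and ndufc2 (-7.33) were also lower in poly(A)+ libraries. The genes map4 (4.80), sec16a (4.80), atxn2l (4.80) and taf4 (4.63) were higher. By limma 691 of 18547 genes were higher and 7788 lower in poly(A)+ libraries, and 1842 and 5437 in TPM, which is 25.3% higher instead of 8.15%. The median log2 difference of all genes was -0.64, or -0.13 in TPM. The lower genes included 66 of 74 of oxidative phosphorylation, 75 of 85 on the ribosomal protein list, 12 of 18 histones, 18 of 48 of the cell cycle and 15 of 31 of oocyte and germ plasm. At 18 to 23.5 hpf 1635 genes were higher and 830 lower, or 1692 and 593 in TPM. The cilium gene rsph1 was higher in poly(A)+ libraries, at 2.15 against 0.0402 M (5.92, SE 0.29, n = 12 pairs), as were gypc (5.38), c9orf116 (5.21), pcp4l1 (4.85) and dpysl5 (4.63). Replication-dependent histone genes, whose messenger RNAs end without a poly(A) tail, were lower in 13 of 18 cases, with hist1h4k at 0.00137 against 1.12 M (-7.46, SE 0.17), hist1h2bj at -6.67, hist1h2al at -6.60 and hist1h4d at -5.81. The gene parp2 was lower as well, at 0.277 against 20.7 M (-6.29, SE 0.14). Of 35 neural genes 10 were higher, with six3 at 3.22, and of 38 Hox genes 8 were higher, with hoxb1 at 2.87. Of the 691 genes higher at 0 to 1.5 hpf, 422 were also higher at 18 to 23.5 hpf, against 60.9 if the sets were independent, and 329 genes were lower at both times.

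**Figure D4:**
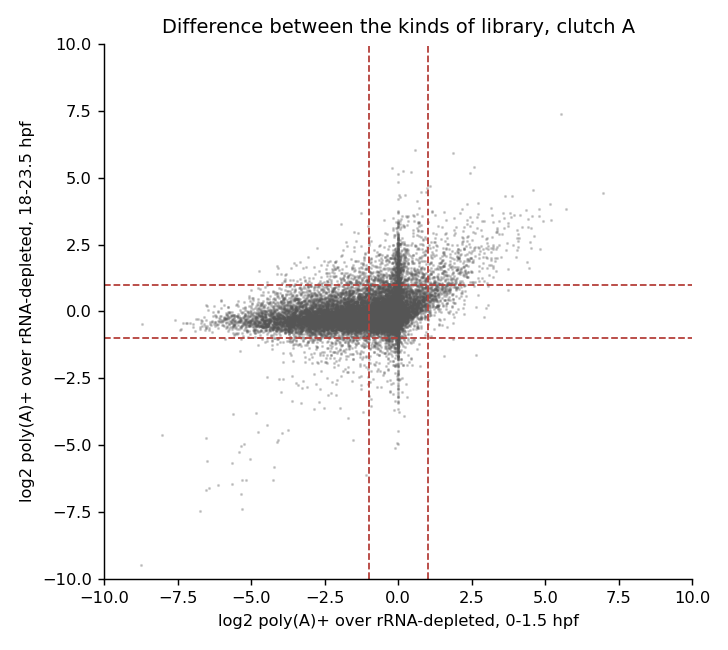
Log2 of poly(A)+ over depleted transcripts per embryo in clutch A at 0 to 1.5 hpf (horizontal axis) against 18 to 23.5 hpf (vertical axis), with a point per gene and dashed lines at -1 and 1. More genes lay below 0 at the earlier time, where 7788 were called lower and 691 higher, than at the later time, where 830 were lower and 1635 higher.

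The 2 clutches were compared at 49 shared time points. Averaged over these, 217 genes were higher and 48 lower in clutch A by limma, paired by time point (222 and 43 in TPM). The kinetochore motor gene cenpe was 1.28 M in clutch A and 0.233 M in clutch B at 0 to 1.5 hpf, and its log2 difference over all time points was 2.28 (SE 0.09). The chromatin regulator ankrd11 differed by log2 2.44, ankrd12 by 2.47, golga4 by 2.36 and the neuropeptide precursor gene pnoc by 2.59 (SE 0.23). In the other direction were msra.1 (-1.33), caskin2 (-1.19), cyp2f1 (-1.14), mettl4 (-1.12) and dhx32 (-1.01). Of the 217 genes, 201 had the same sign in all 7 windows up to 24 hpf, and of the 48, 27 did. A difference of at least 1 log2 in all 7 windows was found for 62 of the 217 and 1 of the 48. The genes were chosen on these same time points, so agreement in sign is partly built in. In the fit that was not paired by time point, the change from window to window differed between clutches for few genes. Limma called 0 genes at 2 to 3.5 against 0 to 1.5 hpf (193 at an unadjusted p under 0.05). For the next 3 comparisons in order, 1, 41 and 22 genes changed more upward in clutch A and 46, 27 and 3 more downward. Of these caskin2 (log2 2.32) was the 1 gene, and crisp2 (-1.09), pnoc (-1.90) and a gene without a symbol (-1.15) were the 3, named because the counts are small. The largest differences from 2 to 3.5 to 6 to 8.5 hpf were those of rad51d (-2.18), c9orf100 (-1.83), tex9 (-1.37), htatsf1 (-1.32) and senp7 (-1.29). The gene st6gal2 (2.53) rose more in clutch A, and the endothelial gene sox7 (-2.76) changed less upward in clutch A, from 6 to 8.5 to 13 to 17.5 hpf. Paired by time point, a fit chosen after seeing the data, the counts were 12 and 5, 15 and 463, 130 and 73, and 99 and 13. The number of such genes thus depended on the pairing.

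The timing of poly(A)+ transcripts was read from the authors' smooth curves, every 0.5 h, as the time at which a gene that stood under 10% of its maximum over 0 to 2 hpf reached 50% of it, up to 24 hpf. Such an onset is not the first presence of a transcript, since 75 of 85 genes on the ribosomal protein list and 66 of 74 of oxidative phosphorylation were higher in depleted than in poly(A)+ libraries at 0 to 1.5 hpf. In 3202 genes with such an onset in both clutches, clutch A was earlier by a median of -0.142 h (quartiles -0.563 and 0.273 h), and 80.3% of genes lay within 1 h. In clutch A the first of the early zygotic genes was sia2, at 4.07 hpf, and the median of 46 such genes was 6.15 hpf. The medians were 5.65 hpf for 5 cell cycle genes, 10.5 hpf for 18 genes of epidermis and cement gland, 10.5 hpf for 13 kidney genes, 12.8 hpf for 32 Hox genes, 13.5 hpf for 26 neural genes, 13.6 hpf for 17 multiciliated cell genes, 13.6 hpf for 7 heart genes, 15.6 hpf for 2 pancreas genes, 17.0 hpf for 73 ribosomal protein genes, 17.7 hpf for 31 oxidative phosphorylation genes, 18.1 hpf for 27 muscle genes, 18.6 hpf for 10 blood genes, 19.2 hpf for 10 liver genes and 20.8 hpf for 9 eye and lens genes. The myogenic factor gene myf5 had its onset at 8.15 hpf and foxj1 at 8.58 hpf. These times are descriptive, since 2 clutches give no replicate test of timing. The maximum is the one reached by 24 hpf, so the onset of a gene still rising then depends on this end. This limits the late medians most. The maximum of hbd, with an onset at 21.7 hpf, was 11.5 M up to 24 hpf and 267 M up to 66 hpf. The onset of hoxd8 moved from 11.8 to 20.7 hpf when read up to 66 hpf.

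Hox genes are known to turn on in the order of their place in each cluster, and this order was tested over the whole course of clutch A. Across 38 Hox genes, onset rose with paralogue number, with Pearson r = 0.48 (2-sided permutation p = 0.00113) and Spearman rho = 0.47 (p = 0.00316), where genes are not independent replicates. The 3 genes of group 13 lie equally far from the median paralogue number, farther than all others. Without 2 of these 3 r was 0.38, and with onsets read from 0 to 24 hpf r was 0.64. This was the 1 relation tested of its kind. The medians were 9.63 hpf for 3 genes of paralogue group 1 and 23.1 hpf for 3 genes of group 13, but groups 6 to 9 had medians between 12.1 and 12.7 hpf, before groups 2 to 5. Within clusters rho was 0.27 for 11 genes of cluster a, 0.18 for 9 of b, 0.55 for 10 of c and 0.86 for 8 of d. The first was hoxd1, at 8.38 hpf, and the latest were hoxa13, at 39.9 hpf, hoxc12, at 32.3 hpf, and hoxa4, at 31.6 hpf.

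**Figure D5:**
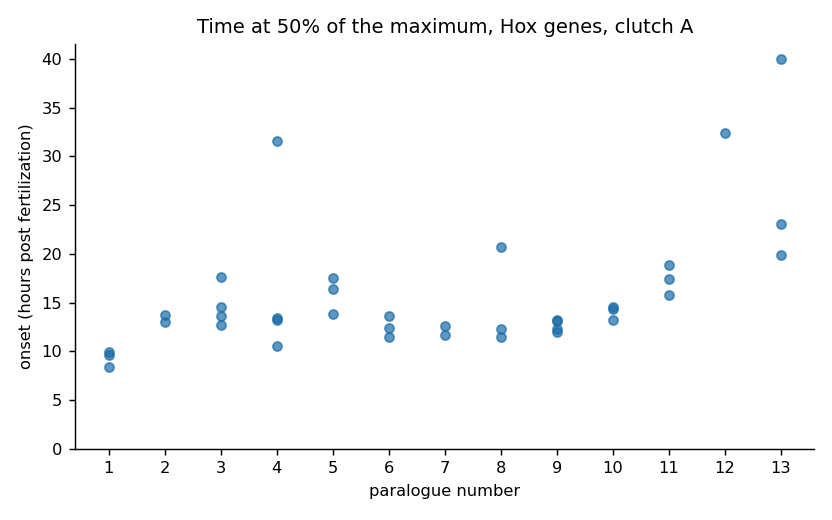
Onset (hpf, vertical axis) of 38 Hox genes in clutch A against paralogue number (horizontal axis), with a point per gene of all 4 clusters. The median onset was 9.63 hpf in paralogue group 1 and 23.1 hpf in group 13.

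The fastest accumulation of poly(A)+ transcripts per embryo was read from the same curves. Up to 66 hpf the mitochondrial gene cox3 reached 25.3 M per h at 59 hpf, the cold-induced RNA-binding protein gene cirbp reached 25.2 M per h at 10 hpf, and mylpf, act3, actc1 and ckm, all of muscle, reached 21.0, 20.8, 18.9 and 16.3 M per h at 59 hpf. The elongation factor gene eef1a1 reached 15.7 M per h at 9.5 hpf, hbd 14.0 M per h at 47 hpf, the cytoskeletal actin gene actg1 13.1 M per h at 14 hpf and eef1a1o 13.1 M per h at 8.5 hpf. For cox3, mylpf, act3 and ckm the largest difference of measured values over 2 h also started at 58 hpf. Measured values carry the same scale as the curves, so this is no independent check. The deposited total of clutch A rose from 30.4 G at 58 hpf to 33.6 G at 60 hpf. How far the shared 59 hpf follows this rise of the total was not tested. Up to 9 hpf the largest rates were those of cirbp (23.9 M per h), eef1a1 (15.0), eef1a1o (13.1), hmgb2 (10.8) and hnrnpa1 (10.8). Differences of measured values over 2 h moved 8 of the 10 by over 1.5 times, cox3 to 60.9 M per h. The largest measured differences of cirbp and actg1 start at 50 hpf and so rest on the 52 hpf library. The order changed as well. By measured values cox3 stayed at rank 1, while cirbp moved from rank 2 to 13, ckm from 6 to 15, eef1a1 from 7 to 16, actg1 from 9 to 21 and eef1a1o from 10 to 69, and rps29, at rank 11 in the curves, took rank 2.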

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

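The tests of an offset in time between the clutches, of a loss of transcripts as in the 52 hpf library and of a fixed loss in depleted libraries were written down before their results were seen, and the other tests weighed here, with the splits of the samples, only after.

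Of 72 groups of libraries and measures with 4 to 10 libraries, 1 held a library far from the others, where chance gives about 1 in 20. In the clutch B library of 16.5 hpf the 10 most abundant genes took 7.81% of the summed gene transcripts, without spike-ins, the highest of the 13 to 17.5 hpf window.

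Differences between the clutches in how genes changed were called for 47 genes from 2 to 3.5 to 6 to 8.5 hpf, 68 from there to 13 to 17.5 hpf and 25 from there to 18 to 24 hpf, by a test of the difference itself. In the first of these clutch A changed less upward or more downward than clutch B for senp7 (log2 -1.29), htatsf1 (-1.32), tex9 (-1.37), c9orf100 (-1.83) and rad51d (-2.18). In the second it did so for syn2 (-1.47), c3orf31 (-1.55), pnoc (-2.05), txndc6 (-2.33) and sox7 (-2.76), and changed more upward or less downward for st6gal2 (2.53), cyp2a13 (2.24), c11orf54 (2.17), dhx32 (2.11) and c9orf100 (2.05).

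Differences between poly(A)+ and depleted libraries in how genes changed were called for 6562 genes from 0 to 1.5 to 2 to 3.5 hpf and for 3271 from there to 6 to 8.5 hpf. In the first, the poly(A)+ change was lower for trim37 (log2 -2.03), anubl1 (-2.04), eif2ak3 (-2.28), melk (-2.32) and mir427 (-3.24), and higher for hs3st1 (4.38), dpp8 (4.30), dusp11.2 (4.21), slc38a9 (4.05) and wdr46 (4.05). In the second it was lower for fzd1 (-1.77), rab11fip5 (-1.84), menf.2 (-1.85), map4 (-2.15) and cpeb1 (-2.10), and higher for mrps25 (4.48), ska2 (4.46), tubb2c (4.42), mixer (4.83) and ndufc2 (6.09).

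The rise of 6411 genes in poly(A)+ libraries from 0 to 1.5 to 2 to 3.5 hpf was weighed first. A change of spike-in delivery or scale would vanish in TPM, where 4555 genes were still higher, and this argues against it as the whole cause. New transcription of these genes would raise them in the depleted libraries too, where their median log2 change was -0.0686, which argues against it. A change in poly(A) capture without a change in the amount of RNA would appear as a difference between the kinds of library, and 5975 of the 6411 genes were called in that test. Longer poly(A) tails on stored maternal messenger RNAs may therefore account for the rise, as a hypothesis found and tested on the same data, since tail lengths were not measured here.

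More genes were higher (217) than lower (48) in clutch A than in clutch B at matched times. A different scale of the clutches would vanish in TPM, where 222 genes were higher, and an offset in developmental time would lower the number of called genes from 265 when clutch B is shifted, but the lowest number over shifts of up to 1 h was 229. This argues against a scale, and against a constant offset of up to 1 h as the whole cause. Each shift was the same at all time points, so an offset that varies over the course was not tested. At that shift of 1 h 166 genes were higher and 63 lower, so an offset may add to the excess, and larger shifts were not tested. A loss of certain transcripts like that in the 52 hpf library, which stands apart from its neighbours, stays open. In that library the 217 genes had a median log2 deviation of -0.8671 relative to all genes, below the lowest of matched random sets (-0.58), while the 48 genes stood at 0.63. The same kind of loss may thus contribute to the difference between clutches, and a genetic difference between the parents of the clutches stays open, untested.

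At 18 to 23.5 hpf 1635 genes were higher in poly(A)+ than in depleted libraries. A difference in scale between the kinds would vanish in TPM, where 1692 genes were higher, which argues against it. A fixed loss of certain transcripts in the depleted libraries predicts that the same genes are higher at both ends of the course. Of the genes higher at 0 to 1.5 hpf, 61.07% were also called higher at 18 to 23.5 hpf, against 8.81% of all genes, so such a loss may account for part of the pattern. No biological explanation was tested.

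Other splits of the same samples showed how many genes other groupings call. For 2 to 3.5 against 0 to 1.5 hpf the real split called 6480 genes, and the highest other of 100 splits 5596. The counts were 4555 and 2160 for 6 to 8.5 against 2 to 3.5 hpf, and 9600 and 0 for 13 to 17.5 against 6 to 8.5 hpf. They were 4838 and 743 for 18 to 24 against 13 to 17.5 hpf, and 9360 and 1140 for 49 to 66 against 18 to 24 hpf. For the level of the clutches they were 265 and 0, and for the kinds of library at 18 to 23.5 hpf 2465 and 1362. The differences between kinds gave 6562 and 5697 (35 splits) in the first comparison, and 3271 and 1996 in the second. In each of these only the real split, 1 in number, gave as many genes. Its windows join neighbouring time points of a smooth course, which other splits mix, so it was likely to call the most genes. Splits of the clutch level and of the kinds exchange labels at single time points, as if neighbouring ones were independent. These splits therefore cannot exclude chance, and for the clutches 1 stands against 1. At 0 to 1.5 hpf the kinds of library allow 8 splits, too few for a share under 0.05 (8479 genes, 6219 in the highest other). For the differences between clutches in the unpaired fit, the first comparison allows no statement, since its real count is 0, which all 100 splits reach in any case (2845 in the highest other). Chance cannot be excluded in the other 3, where 11 of 100 splits gave as many as 47, 5 as many as 68 and 6 as many as 25. The highest other splits of these 3 called 991, 431 and 246 genes, several times the real count, which points to a structure of the samples. Paired by time point, the real counts rise to 17, 478, 203 and 112. There 35 and 16 of 100 splits gave as many in the first and second comparison, and 3 each in the third and the fourth. This fit was chosen after seeing the data and the shares were not adjusted for the number of tests. Chance can therefore not be excluded in any of these comparisons. The highest other splits called 3415, 1364, 630 and 567 genes, again several times the real count.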

How the results depend on the processing

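The scale from each library's own ERCC sum, the fits without 22.5 hpf in both clutches and paired by time point, and the joint table for the clutch levels were chosen only after the results were seen. The 44 group results had 372 values under alternatives, of which 328 kept direction and side of the threshold, or stayed within 1.5 times for counts. Of 8959 values for 640 gene results, 8785 did so, 166 no longer passed and 8, all rates, moved. Leaving out each time point in turn gave 5787 to 7164 called genes at 2 to 3.5 against 0 to 1.5 hpf and 4232 to 5028 at 6 to 8.5 against 2 to 3.5 hpf. The depth is unknown, since no read counts are given, so what it limits could not be set. Alternatives fixed earlier with the original or the repeat library alone were not run, since the repeats have no columns. The cause was not tested for any value below, unless named.

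With a pseudocount of 2 TPM, which shrinks changes of low genes by construction, 18 to 24 against 13 to 17.5 hpf gave 2856 genes higher and 270 lower, the clutch difference gave 0 and 29 at 6 to 8.5 hpf and 5 and 1 at 18 to 24 hpf, the clutch level 128 and 12, the kinds of library at 18 to 23.5 hpf 424 lower, and the kind difference at 6 to 8.5 hpf 116 lower. With 0.1 TPM the clutch difference gave 2 higher at 6 to 8.5 hpf and 13 at 18 to 24 hpf, and the clutch level 112 lower. Without a filter the clutch difference at 6 to 8.5 hpf gave 3 higher.

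In TPM, which removes the growth of the total by construction, 203 genes were lower at 2 to 3.5 hpf, 2515 higher and 722 lower at 18 to 24 hpf, and 4093 higher and 3614 lower at 49 to 66 hpf. The clutch difference gave 1, 4 and 5 higher at 2 to 3.5, 6 to 8.5 and 18 to 24 hpf, the kinds of library at 0 to 1.5 hpf 1842 higher, and the kind difference 203 lower at 2 to 3.5 hpf and 1687 higher and 532 lower at 6 to 8.5 hpf.

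With each library's own ERCC scale the clutch difference gave 17 lower at 6 to 8.5 hpf and 14 higher at 18 to 24 hpf. The totals no longer passed at 2 to 3.5 hpf in clutch A (log2 0.42), clutch B (0.48) and depleted libraries (-0.0779), and at 6 to 8.5 hpf in clutch A (0.26), while the clutch total reversed to 0.0183. With the joint table the clutch total passed, at -0.0157, where the authors scaled both clutches together. Without 22.5 hpf in both clutches the clutch difference gave 1 and 2 higher at 2 to 3.5 and 6 to 8.5 hpf. Paired by time point it gave 12 higher and 5 lower, 15 and 463, 130 and 73, and 99 and 13 over the first 4 comparisons. With time point as a replicate block, pairing the clutches, the first 4 comparisons gave 6337 higher and 67 lower, 3226 and 1270, 5995 and 3566, and 4382 and 441.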

Other observations

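Both hypotheses on the libraries below were tested only after their pattern was seen, and the values of clutch timing had no test.

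The difference in onset between the clutches varied with the time of onset. Clutch A was later by a median of 0.201 h for 550 genes with an onset from 12 to 14 hpf and 0.223 h for 618 genes from 14 to 16 hpf. The median difference was -0.392 h for 566 genes from 16 to 18 hpf and -0.82 h for 425 genes from 18 to 20 hpf. It was -0.642 h for 132 genes from 20 to 22 hpf and 0.054 h for 9 genes from 22 to 24 hpf. Each group with an onset before 12 hpf had a negative median. Genes were grouped by their onset in clutch A, which is also 1 side of the difference, so the grouping itself can shape this pattern. Among the lists the median difference was -0.78 h for 27 skeletal muscle genes, -0.74 h for 31 genes of oxidative phosphorylation, -0.52 h for 73 on the ribosomal protein list and 0.1 h for 17 multiciliated cell genes.

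The 6 time points of clutch A with a repeat library may be those whose library stood apart from its neighbours. Whether their columns hold the original, the repeat or both is not known. Ranked by the median absolute log2 deviation from the neighbours, they took ranks 1 (52 hpf), 4 (64 hpf), 5 (11.5 hpf), 6 (33 hpf), 8 (30 hpf) and 12 (21.5 hpf) of 88, with a mean rank of 6 (1-sided permutation p = 1e-05, the smallest possible). The deviation was 0.623 at 52 hpf, against a median of 0.0862 in clutch A. The clutch B library of 22.5 hpf, at 0.536, has no repeat.

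The ERCC sums of poly(A)+ and depleted libraries of clutch A varied together over 48 shared time points, with Pearson r = 0.804 (permutation p = 1e-05, the smallest possible; adjusted p = 3e-05 over 3 relations), Spearman rho = 0.788 (permutation p = 1e-05, adjusted p = 3e-05) and r = 0.761 without the 2 farthest time points. Between poly(A)+ libraries of the 2 clutches r was 0.208 (permutation p = 0.152, adjusted p = 0.153) and rho 0.24 (permutation p = 0.0968, adjusted p = 0.0968), with r = 0.282 without the 2 farthest. Between depleted libraries and clutch B r was 0.21 (permutation p = 0.153, adjusted p = 0.153) and rho 0.328 (permutation p = 0.0232, adjusted p = 0.0349), with r = 0.34 without the 2 farthest. Per the labels, spike-in RNA was added to the homogenised embryos, and so was combined with embryo RNA before the libraries were made. What stays open is whether both kinds of library of a clutch A time point were made from the same mix, as the relation in clutch A may mean.

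ArrayControl spike-in sequences took a median of 0.273% of TPM in clutch B and at most 0.000445% in the poly(A)+ libraries of clutch A.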
